A study of Mus musculus with 4 samples.

How the data were processed

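Total RNA of 4 BaF3 lines was measured on Affymetrix mouse 430_2 arrays by the standard Affymetrix protocol, per the labels' protocols. The lines were parental, with BCR-ABL, with ICSBP and with both, with 1 array each, and each sample's condition was taken from its title. The deposited values are linear signal intensity per probe set. The design text states a threshold of 50, and the deposited intensity values had a minimum of 50 and a median of 100.0 over the 45101 probe sets on each array, which shows scaling of the arrays to a common median and a floor on low values. The summarisation software, the scaling method and the Present flags are not given in the sources used here. The design text also states that genes needed 1 Present flag and a 3-fold ratio to parental cells, and that 1431 genes were grouped into 15 clusters with K-means in Gene Cluster 3.0.

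The arrays were compared on the 21069 probe sets above the floor on all 4. Their median log2 signal ranged over 0.45 between arrays, above the preset limit of 0.2, so each array was divided by a factor that brought these medians to the lowest. The factors were 1.10 for parental, 1.37 for BCR-ABL, 1.26 for ICSBP and 1.00 for BCR-ABL plus ICSBP. Signals were then raised to the floor of 50 and log2 was taken. The ratio of 3' to 5' signal of the actin control ran from 1.21 to 1.30, and that of the Gapdh control from 0.798 to 0.866.

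Probe sets were named from the platform's probe annotation, which can be old. Of 45101 probe sets, 64 were controls, 34958 had 1 gene symbol, 932 had several and 9160 were not listed. The Entrez identifier of 34754 of those with 1 symbol was found in a RefSeq gene table, and 204 were not found. No symbol was changed. Each of 18193 genes was represented by its probe set of highest mean log2 signal among those with 1 symbol. The 10092 probe sets with several symbols or unlisted were counted and not named.

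A gene was measured in a comparison where at least 1 of the 2 arrays was above the floor. Its value is the log2 ratio of those arrays, and it counted as different from 3-fold on. A ratio against an array at the floor is a lower bound and is written as at least that fold. List medians take such a ratio at its bound. The 5 comparisons were each construct against parental, both constructs against each single one, and both against parental. The difference of the ICSBP effect between backgrounds is a difference of log2 ratios over all 4 arrays. No test was made, because 1 array per condition has no replicate spread and a fit of main effects alone would take the interaction as its error. Over genes with several probe sets above the floor, the ratios of 1 gene's probe sets had an SD of 0.46 to 0.49 (log2), or 0.32 to 0.35 at a mean signal of at least 200. The number of arrays limits the precision.

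The 34 gene lists were written before the values were seen, from general knowledge. For each, the members at least 3-fold higher and lower were counted, and the median log2 ratio was placed as a percentile among 10000 random lists of the same size matched on mean log2 signal in 20 bins. It describes these arrays and is no p-value. The genes named followed a preset rule. For each comparison it took the 6 highest and 6 lowest ratios among genes above the floor on both arrays with the brighter at 200 or more. It added, in each direction, the 4 brightest genes with the other array at the floor, and up to 4 members per list with the largest difference. It took Ccl6, Ccl9, Irf8, Abl1 and Bcr always, and the 6 highest and 6 lowest differences of the ICSBP effect. Genes named in the text only as members of overlaps, clusters or short counts were chosen after their values were seen. Predicted and clone symbols were counted and not named.

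Overlaps of called genes were set beside the number that independent lists of those lengths would share, as were calls of opposite direction, which were counted against chance only after the data were seen. Counts over the 3 ratios to parental, which share that array, were set beside 100 simulations of 3 unchanged arrays against it. K-means used 15 clusters with seed 1 on the 3 log2 ratios. Alternatives were a floor of 100, quantile normalization, the median of a gene's probe sets, leaving out probe sets shared between transcripts, a minimum of 200 for the brighter array, and fold thresholds of 2 and 5. The median of probe sets was taken over their log2 signals on each array, so different probe sets can supply it on different arrays. Chosen after seeing the data were the values as deposited and scaling on the 38 added bacterial and phage control probe sets.

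The code was tested on simulated data of the BCR-ABL against parental comparison with 18193 genes, 200 of them changed. It called 3.5% of the changed genes at 2-fold, 87.0% at 4-fold and 100% at 8-fold, and 0 unchanged genes, with a noise SD of 0.235 (log2) per array for all genes. That is less than dim genes show. With noise by signal, at an SD of 0.449 in the dimmest and 0.113 in the brightest of 20 bins, it called 3.5%, 94.5% and 99.5% of the changed genes and 58, 61 and 68 unchanged genes. This second simulation was added after the data were seen. All simulated noise, also that over the 3 ratios, was normal. Its SD came from a robust spread over genes of the difference of the ICSBP effect. It can thus count real differences of effect as noise, and it leaves out wider tails. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.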

Results

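Gene expression was measured in BaF3, a mouse pro-B cell line that needs interleukin 3 to grow, on Affymetrix mouse 430_2 arrays. The 4 conditions form a 2 by 2 design: the parental line, a line with BCR-ABL (the fusion tyrosine kinase of chronic myeloid leukaemia), a line with ICSBP (interferon consensus sequence-binding protein, the transcription factor encoded by Irf8), and a line with both. All were grown with conditioned medium of WEHI-3B cells as the source of interleukin 3, and none was treated further. There was 1 array per condition, so no difference given here has a replicate check and no p-value is given. Each array reported 45101 probe sets, of which 33.7% to 34.5% lay at the floor of 50 signal units. After centring, 16270 of 18193 named genes were above the floor on at least 1 array and 10091 on all 4. Differences are ratios of 2 arrays in centred signal units, and the number of arrays limits their precision.

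The construct genes were examined first. Irf8 had a signal of 145 on the parental array and lay at the floor on the other 3 in 1 probe set, and its other probe set lay at the floor throughout. Neither probe set therefore showed the ICSBP construct on the arrays labelled ICSBP and BCR-ABL plus ICSBP. The construct's sequence is not given in the sources used here, so whether these probe sets could read it is unknown, and they do not check the labels. Abl1 had signals of 688, 656, 706 and 791 on the parental, BCR-ABL, ICSBP and BCR-ABL plus ICSBP arrays, and Bcr 420.2, 332, 441 and 388. These small differences likewise do not check the label BCR-ABL, and every direction below rests on the arrays as labelled.

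The series title asks about CCL6 and CCL9, CC chemokines that attract myeloid cells, in protection by ICSBP from leukaemia driven by BCR-ABL. Both genes were brightest on the array labelled ICSBP. Ccl9, by its brightest probe set, had signals of 116, 139.7, 6902 and 2012 on the parental, BCR-ABL, ICSBP and BCR-ABL plus ICSBP arrays. It was 59.4-fold higher with ICSBP than in parental cells, and 14.4-fold higher with both constructs than with BCR-ABL alone. Ccl6, by its brightest probe set, lay at the floor on the parental array and read 172, 2582 and 771 on the other 3. It was at least 51.6-fold higher with ICSBP than in parental cells, and 4.47-fold higher with both constructs than with BCR-ABL alone. With BCR-ABL present in addition to ICSBP, Ccl6 was 3.35-fold lower and Ccl9 3.43-fold lower than with ICSBP alone. The other probe set of Ccl9 read 122.8, 159.5, 4531 and 1452, and that of Ccl6 120.1, 61.0, 910 and 184, with the same direction in these 3 comparisons. For BCR-ABL against parental cells the probe sets of Ccl6 went opposite ways, at log2 ratios of at least 1.78 and of -0.98, so no direction is drawn from them.

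**Figure D1:**
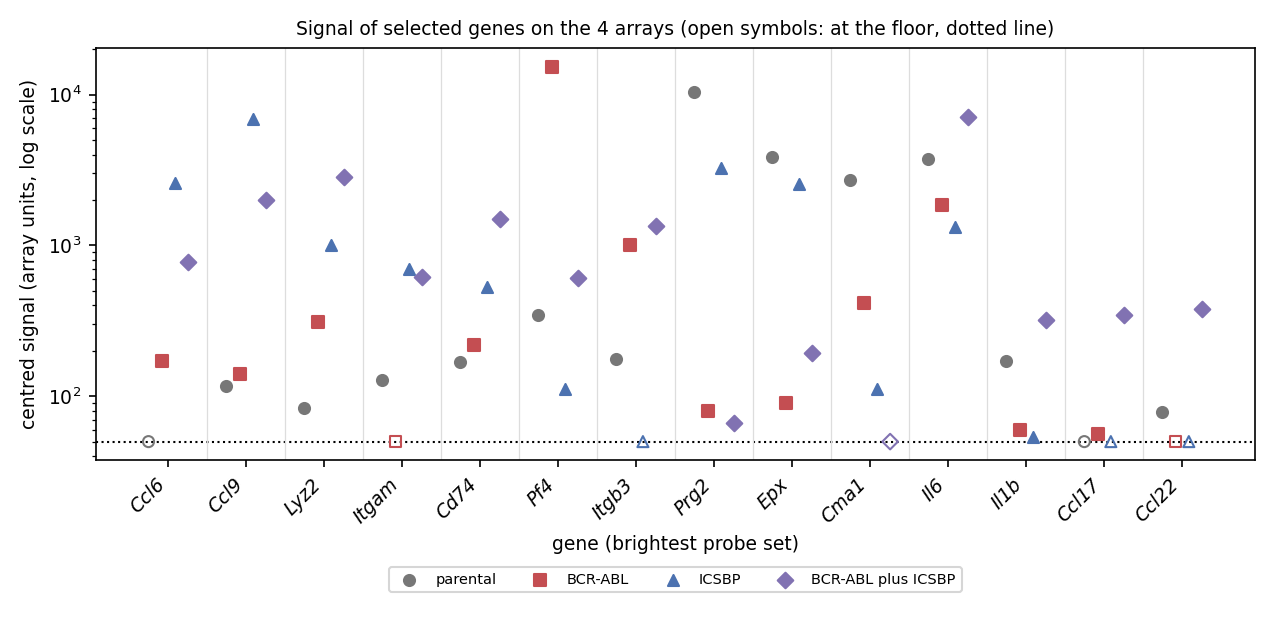
Centred signal (log axis, array units) of 14 genes on the 4 arrays, 1 point per array, with open symbols for values at the floor of 50 (dotted line). Ccl9 read 6902 and Ccl6 2582 on the ICSBP array, against 116 and the floor on the parental array, while Pf4 read 15368 on the BCR-ABL array and Prg2 10346 on the parental array.

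The comparison of BCR-ABL with parental cells asks what the kinase changes without ICSBP. Prg2, the eosinophil major basic protein, was 130.0-fold lower on the BCR-ABL array (10346 to 79.6 units), Epx, eosinophil peroxidase, 42.4-fold lower, and Ngp, the neutrophilic granule protein, at least 71.1-fold lower. The neutrophil list had 0 of 11 measured members at least 3-fold higher and 2 lower (Ngp and Mmp9, the latter under 3-fold in 4 alternatives, at -0.84 with a floor of 100, log2), with a median log2 ratio of -1.18, at percentile 0 of 10000 random lists matched on signal. The mast cell and basophil list had 5 of 16 members lower, Prg2, the mast cell chymase Cma1 (6.52-fold), Ms4a2 (-1.14 by the median of its probe sets, log2), and Cd200r3 and Mcpt8, both chosen after their values were seen, and 1 higher, the granzyme Gzmb (5.52-fold). Its median was -0.48 (percentile 0.09), which became 0.12 with scaling on the added control transcripts.

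The inhibitory Fc receptor Fcgr2b was 13.7-fold lower on the BCR-ABL array, with a smallest log2 ratio of -2.91 over the alternatives. The chemokine receptor Cxcr4, which binds CXCL12, was 7.78-fold lower, and the interleukin 2 receptor subunit Il2ra 3.49-fold lower. Csf2rb2, a beta subunit of the interleukin 3 receptor, was 3.604-fold lower, and its relative Csf2rb 2.903-fold lower (33073 to 11393 units), which is under the threshold. The cytokine receptor list had 2 of 26 members lower (Csf2rb2 and Il2ra) and 0 higher.

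Pf4, platelet factor 4, was 44.4-fold higher on the BCR-ABL array (346 to 15368 units), and the integrin subunits Itgb3 and Itga2b, which form the platelet fibrinogen receptor, 5.66-fold higher and 3.39-fold higher. The erythroid and megakaryocyte list had 2 of 14 members higher (Pf4 and Itga2b) and 0 lower, with a median of 0.43 (percentile 99.8). Dusp4, a phosphatase that acts on ERK, was 3.67-fold higher, and it was the 1 of 24 ERK feedback genes past the threshold, at a list median of 0.32 (percentile 99.8). Among NF-kB targets 2 of 19 were higher, the cytokine Ltb (5.51-fold) and the inhibitor Nfkbia (3.04-fold), with a median of 0.45 (percentile 99.98), and the list was as high for ICSBP against the same parental array (0.49, percentile 99.97). Nfkbia was under 3-fold after quantile normalization (1.51), by the median of its probe sets (1.53) and with scaling on the added controls (1.57, log2). The STAT5 target list had 0 of 21 members higher and 2 lower, Socs3 (4.17-fold, but -0.65 by the median of its probe sets, log2) and Il2ra. Its median was 0.35 (percentile 99.8), or -0.0329 by the median of each gene's probe sets, and 0.24 (percentile 97.3) for ICSBP against parental. The stem and progenitor list had 2 of 14 members higher (Mycn by its brightest probe set, and the transcription factor Lmo2 at 5.47-fold) and 2 lower (Flt3 and Meis1, both under 3-fold with a floor of 100), at a median of 0.48 (percentile 99.9). Percentiles this high were common over the lists of this comparison. Among them were p53 targets (99.95), cholesterol synthesis (99.9) and cell cycle inhibitors (99.8), so the percentiles do not set the lists of this paragraph apart. The Mycn probe set read 120.1 on the parental array and 31265, 33565 and 48707 on the BCR-ABL, ICSBP and BCR-ABL plus ICSBP arrays, while the gene's other probe sets had log2 ratios of 1.0003 and 0.51 for BCR-ABL and -0.04 and -0.29 for ICSBP against parental.

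Over all genes, 325 of 14522 measured were at least 3-fold different on the BCR-ABL array, 96 higher and 229 lower. Simulations of this comparison with noise that depends on signal called 58 to 68 unchanged genes. That noise was normal and set from these arrays without replicates, so how many of the 325 are noise is not known. In 147 of the 229 the BCR-ABL array was at the floor, so their folds are bounds. The split moved with the scaling: quantile normalization gave 144 higher and 167 lower, the values as deposited 306 and 208, and scaling on the added controls 6 and 1143. Both of the last shift the median of all genes, by 0.34 and -0.92, so gene and list values given under them are taken relative to it.

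The comparison of ICSBP with parental cells asks what the transcription factor changes without the kinase. On the array labelled ICSBP the macrophage and monocyte list had 7 of 30 measured members at least 3-fold higher and 0 lower, with a median log2 ratio of 0.89 (percentile 100). Lyz2, lysozyme, was 12.1-fold higher (83.2 to 1011 units), the lysosomal protease Ctss 12.6-fold higher, the pore-forming protein Mpeg1 at least 10.6-fold higher, and the integrin subunit Itgam, known as CD11b, 5.46-fold higher. Quantile normalization, the values as deposited and scaling on the added controls each gave 8 members higher and 0 lower. Lyz1 was also called, but 1 of its 3 probe sets went the other way (-1.41 without probe sets shared between transcripts), and lysozyme genes are near copies. Of the 5 phagocyte oxidase genes 1 was higher, Ncf1 (3.75-fold, 1.43 by the median of its probe sets on the log2 scale), and the list's median was 0.90 (percentile 99.98).

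Lcn2, which binds bacterial siderophores, was 14.9-fold higher, and Cfp, the complement factor properdin, at least 23.98-fold higher, although the other probe set of Cfp went the other way (-1.05). Ghr, the growth hormone receptor, was 41.9-fold higher in the shown probe set and higher in all 3 measured. The neutrophil list had 2 of 10 members higher (Lcn2 and S100a8) and 2 lower (Ngp and Csf3r), and S100a8 and Csf3r fell under 3-fold with a floor of 100 (0.91 and -0.87, log2). Its median was -0.41 (percentile 2.44), and 1.24 over the 3 members of at least 200 units. Fcer1a, the alpha chain of the high-affinity IgE receptor, was 17.5-fold higher (53.6 to 936 units), or 3.23 with a floor of 100 (log2). The MHC class I list had 0 of 18 members past the threshold, yet a median of 0.54 (percentile 100), with Tapbp, the peptide-loading protein tapasin, at 1.21.

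The mast cell chymase Cma1 was 24.4-fold lower, the granzyme Gzmb at least 7.05-fold lower and the protease Mcpt8 at least 5.12-fold lower, the last under 3-fold with a floor of 100. The mast cell and basophil list had 5 of 16 members lower, the others being Prg2 and Ms4a2, chosen after their values were seen, and 2 higher (Fcer1a, and Kit, which was under 3-fold with a floor of 100), with a median of -0.73 (percentile 0). Stub1, a ubiquitin ligase, was 39.2-fold lower (2445 to 62.4 units), Lat, an adaptor of T cell receptor signalling, at least 7.85-fold lower, and Nras, a small GTPase of the RAS family, 7.35-fold lower in the shown probe set and lower in all 3. The cytokine and growth factor list had 2 of 21 members lower (Il13 and Il1b, both under 3-fold with a floor of 100) and 1 higher, Ltb (3.55-fold).

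Over all genes, 326 of 14633 measured were at least 3-fold different on the array labelled ICSBP, 154 higher and 172 lower. Quantile normalization gave 197 higher and 140 lower, the values as deposited 326 and 182, and scaling on the added controls 45 and 450.

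The comparison of both constructs with BCR-ABL alone asks what ICSBP changes in cells that carry the kinase, and is the one closest to the series title. On the array labelled BCR-ABL plus ICSBP the chemokine list had 9 of 28 measured members at least 3-fold higher and 1 lower, with a median of 0.90 (percentile 99.99). Besides Ccl9 and Ccl6, these included Ccl22 (at least 7.59-fold) and Ccl17 (6.096-fold), ligands of the receptor CCR4. The count of higher members was 8 after quantile normalization, 9 in the values as deposited and 6 with scaling on the added controls, with 1 lower in each. The lower member was Pf4, which was 25.4-fold lower (15368 to 606 units).

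The macrophage and monocyte list had 8 of 30 members higher and 0 lower (median 0.90, percentile 100), with Mpeg1 at least 12.6-fold higher, Itgam at least 12.4-fold higher and Lyz2 9.11-fold higher. Of the MHC class II antigen presentation list 3 of 13 were higher and 0 lower (median 0.92, percentile 99.2). Cd74, the invariant chain, was 6.83-fold higher (218 to 1489 units) and Ctss, which cleaves it, 3.29-fold higher, whereas the call of H2-DMa (3.204-fold) ended under 4 alternatives (0.71 by the median of its probe sets, log2). Cd52, a glycoprotein of leukocyte surfaces, was at least 40.4-fold higher, and Ghr at least 69.9-fold higher. The inflammatory cytokine genes Il1b and Il6 were 5.33-fold higher and 3.83-fold higher, and the chemokine receptor Cxcr4 was 5.02-fold higher. With a floor of 100 the log2 ratio of Il1b was 1.68. The chemokine receptor list's median was 0.71 (percentile 98.2), and -0.08 with scaling on the added controls.

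Lower on the array labelled BCR-ABL plus ICSBP were again Gzmb (at least 38.9-fold), Stub1 (19.99-fold), Lat (at least 14.7-fold) and Cma1 (at least 8.32-fold). The mast cell and basophil list had 3 of 17 members lower (Gzmb, Cma1 and Cpa3) and 0 higher, at a median of 0.20 that became -0.02 after quantile normalization and -0.16 with scaling on the added controls. Itgal, the integrin subunit of LFA-1, was 5.897-fold lower, and Serpinb1a, an inhibitor of neutrophil proteases, 6.85-fold lower.

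Over all genes, 590 of 14937 measured were at least 3-fold different, 483 higher and 107 lower. Quantile normalization gave 270 higher and 198 lower, the values as deposited 331 and 360, and scaling on the added controls 662 and 21. In 325 of the 483 the BCR-ABL array was at the floor, so their folds are bounds.

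The comparison of both constructs with ICSBP alone asks what BCR-ABL changes in cells that carry ICSBP. Prg2 was 49.01-fold lower (3254 to 66.4 units) and Epx 13.1-fold lower. Fcer1a was 5.78-fold lower, and the mast cell and basophil list had 2 of 15 members lower (Prg2 and Fcer1a) and 0 higher (median -0.63, percentile 0.02). Alas1, the first enzyme of haem synthesis, was 6.95-fold lower (23928 to 3444 units), with a smallest log2 ratio of -2.08 over the alternatives. Il2ra was 3.69-fold lower, and Il4ra, the interleukin 4 receptor alpha chain, 3.35-fold lower, or -1.51 by the median of its probe sets (log2).

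On the array labelled BCR-ABL plus ICSBP the chemokine list had 8 of 29 members higher, among them Ccl22 (at least 7.59-fold), Ccl17 (at least 6.89-fold) and Pf4 (5.41-fold), and 2 lower, Ccl6 and Ccl9 (median 0.57, percentile 98.0). Il1b was 5.97-fold higher, or 1.68 with a floor of 100 (log2), and Il6 5.36-fold higher, with the same value at that floor. Itgb3 was at least 27.0-fold higher, and the erythroid and megakaryocyte list had 2 of 14 members higher (Pf4 and Gp9) and 0 lower, at a median of 0.64 (percentile 99.97). The call of Gp9 ended with a floor of 100 (0.97) and with scaling on the added controls (1.54, log2). Of the ERK feedback genes 3 of 24 were higher and 0 lower (median 0.41, percentile 99.7). Dusp4 was 6.32-fold higher, while Spry1 (3.24-fold) and Fosb (at least 3.09-fold) fell under 3-fold with a floor of 100, after quantile normalization and with scaling on the added controls. Aldh1a1, an enzyme of retinoic acid synthesis, was 15.3-fold higher.

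Over all genes, 498 of 15040 measured were at least 3-fold different, 370 higher and 128 lower. Quantile normalization gave 213 higher and 182 lower, the values as deposited 267 and 323, and scaling on the added controls 304 and 45.

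The effects of each construct in the 2 backgrounds come from separate arrays, so they can be set against each other without a shared control array. Each condition is 1 line, and the titles do not say from which line the one with both constructs was made. If it came from a single-construct line, chance differences of that line could appear in both backgrounds without an effect of the construct. ICSBP went with at least 3-fold higher signal in both backgrounds for 42 genes, where independent lists of the same lengths would share 4.12, and with lower signal for 21 genes against 1.23. Such numbers for independent lists, here and below, take every measured gene as equally likely to be called. Many calls had an array at the floor, such as 88 of the 154 higher with ICSBP against parental. Overlap by chance, also of opposite calls, can therefore exceed these numbers. The 42 included Ccl9, Ccl6, Lyz2, Ctss, Itgam, Mpeg1, Cd74, Lcn2, Ghr, Cd52 and Cfp, and the 21 included Stub1, Cma1, Gzmb, Lat, Pf4, Itgal and Serpinb1a. The 42, of 137 genes called in parental cells, became 40 of 176 after quantile normalization, 42 of 295 in the values as deposited and 31 of 44 with scaling on the added controls, and the 21 became 23, 26 and 12. BCR-ABL went with higher signal in both backgrounds for 11 genes against 2.03, among them Pf4, Dusp4 and Itgb3, and with lower signal for 20 against 1.79, among them Prg2, Epx, Ngp, Fcgr2b, Il2ra and Alas1. The 11, of 93 called without ICSBP, and the 20 became 10, 17 and 3 higher and 22, 30 and 17 lower genes under the same 3 scalings, the 3 out of 6. Of 137 genes higher with ICSBP in parental cells, 78.8% were also higher, by any amount, with ICSBP in BCR-ABL cells, and 0 were at least 3-fold lower, against 1.07 for independent lists. Of 157 lower with ICSBP, 47.8% were lower in BCR-ABL cells, and 9 were at least 3-fold higher, against 4.72. Of 93 higher with BCR-ABL, 73.1% were higher in ICSBP cells and 1, Ccl6, was at least 3-fold lower, against 0.784, and of 212 lower, 52.4% were lower and 10 at least 3-fold higher, against 4.63. The 9 and the 10 share genes and are not separate results. The share of all measured genes higher by any amount was not computed, so these percentages have no base beside them. In the centred values 1700 genes were at least 2-fold higher and 482 lower for both constructs against BCR-ABL. For both against ICSBP the numbers were 1483 and 590. The contrast between the percentages of higher and lower genes can come in part from this lean. These 4 counts of opposite calls became 0, 6, 1 and 4 after quantile normalization, against 2.40, 2.25, 1.581 and 2.04 for independent lists. In the values as deposited they were 10, 7, 11 and 6, against 7.02, 3.25, 5.73 and 2.91. With scaling on the added controls they were 0, 27, 0 and 29, against 0.0743, 18.98, 0.0207 and 21.5. The calls of Pf4 for ICSBP against parental and of Ngp for both against ICSBP are near the threshold, and ended at -1.53 after quantile normalization and at -1.583 with scaling on the added controls. Across the 10091 genes above the floor on all arrays, the ICSBP effects in the 2 backgrounds correlated weakly (Pearson's r 0.176, Spearman's rho 0.0876), as did the BCR-ABL effects (r 0.124, rho 0.0764), and the mean effects of the constructs had an r of 0.0316 (rho 0.0586). Genes are not independent replicates.

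**Figure D2:**
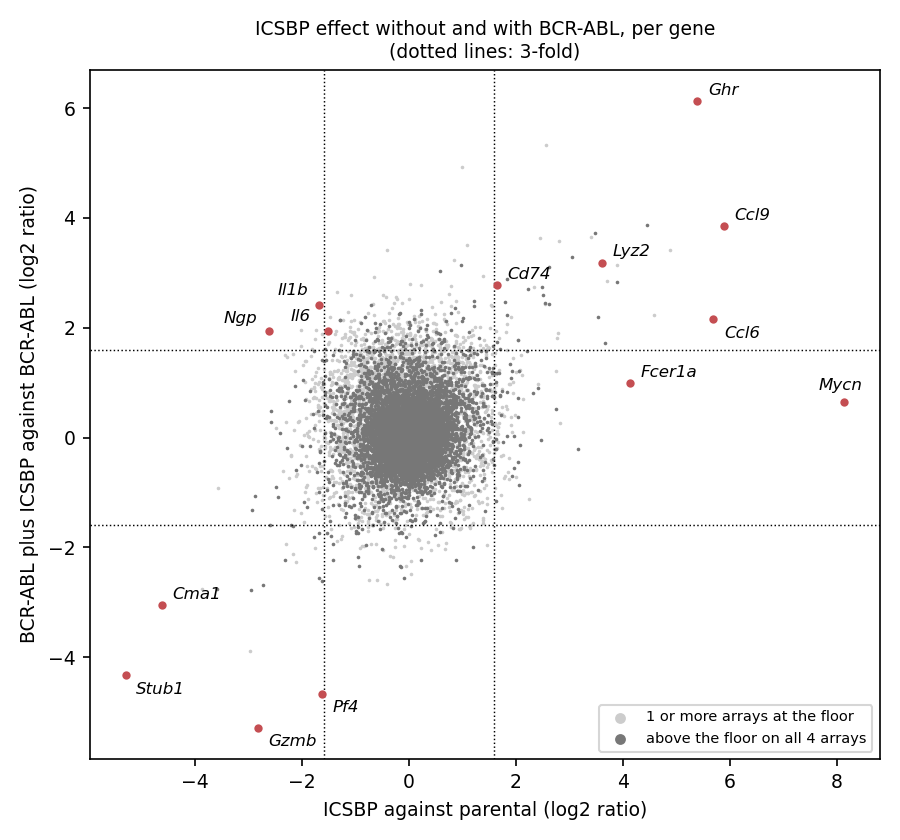
Log2 ratio of ICSBP against parental (x axis) and of BCR-ABL plus ICSBP against BCR-ABL (y axis), 1 point per gene, grey level by whether all 4 arrays were above the floor, with dotted lines at 3-fold. Ccl9 (5.89 and 3.85), Ccl6 (at least 5.69, and 2.16), Ghr (5.39, and at least 6.13) and Lyz2 (3.60 and 3.19) lie in the upper right, and Stub1 (-5.29 and -4.32) and Cma1 (-4.61, and -3.06 or lower) in the lower left.

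For 1146 of 13949 genes the ICSBP effect differed at least 3-fold between backgrounds, 885 with a higher and 261 with a lower value in BCR-ABL cells. The difference carries the noise of 4 arrays, so noise alone passes 3-fold more easily than in a ratio of 2 arrays. No simulation was run for this count, so how much of it is noise is not known. With a floor of 100 it was 230, and with the brightest array at 200 or more 379. Quantile normalization gave 485 and 486, the values as deposited 560 and 891, and scaling on the added controls 2916 and 15. Among genes above the floor on all arrays the largest difference was that of the Mycn probe set described above, 179-fold lower in BCR-ABL cells (8.13 and 0.64), or 4.52-fold by the median of the gene's probe sets. That median is of signals on each array and gave a log2 ratio of 1.41 for ICSBP against parental. None of the gene's other probe sets reached that ratio (highest 1.0003), so the 4.52-fold is no check separate from the brightest probe set. The largest difference with a higher value in BCR-ABL cells was that of Il1b, 17.0-fold, at log2 ratios of -1.67 without and 2.41 with BCR-ABL. Its signals lay near the floor on 2 arrays, and with a floor of 100 the log2 ratios were -0.77 and 1.68 and the difference 5.46-fold. The next one given is Il6, at 10.9-fold (-1.51 and 1.94), with the same value at a floor of 100. Besides Mycn, lower values in BCR-ABL cells were seen for Sgsm3, a regulator of small GTPases (3.15 and -0.21), Fcer1a (4.13 and 0.99), Pf4 (-1.63 and -4.66) and Ccl6 (at least 5.69, and 2.16). No test of these differences was possible with 1 array per condition.

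The comparison of both constructs with parental cells gave 595 of 15235 genes at least 3-fold different, 403 higher and 192 lower. Lyz2 was higher by a log2 ratio of 5.09, Ccl9 17.3-fold higher, Cd74 8.86-fold higher and the chemokine Ccl3 at least 13.2-fold higher, while Prg2 was 156-fold lower, Cma1 at least 54.2-fold lower and F13a1, the A chain of clotting factor XIII, 46.4-fold lower. The NF-kB target list had 5 of 18 members higher and 0 lower (median 0.49, percentile 99.8), Ltb (5.596-fold), Relb (4.84-fold), Tnfaip2 (1.08 without probe sets shared between transcripts, log2), Nfkbia and Traf1, the last chosen after its value was seen. Of the STAT5 targets 3 of 21 were lower, the feedback inhibitor Socs1 (5.56-fold), Il2ra and Osm, and 1 higher, Pim3, whose call ended with a floor of 100 (1.37, log2). Quantile normalization gave 295 higher and 204 lower genes, the values as deposited 347 and 257, and scaling on the added controls 191 and 356.

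**Figure D3:**
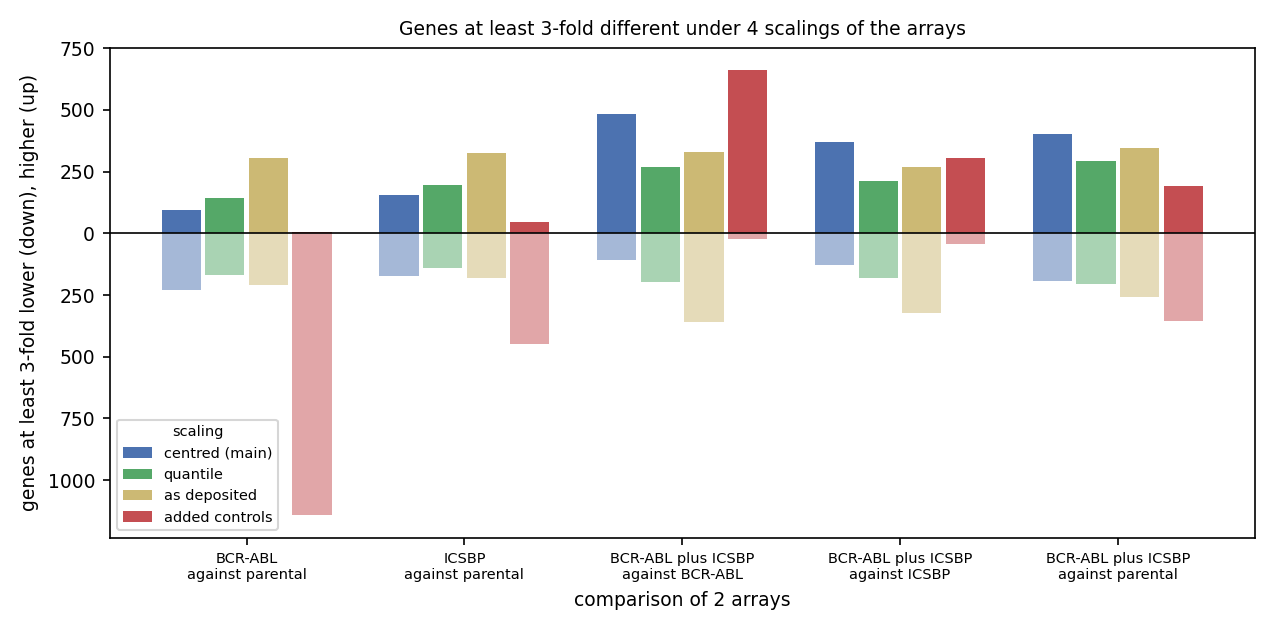
Number of genes at least 3-fold higher (bars up) and lower (bars down) in the 5 comparisons, each of 2 arrays, under 4 scalings of the arrays. For BCR-ABL against parental the counts ran from 96 higher and 229 lower in the centred values to 306 and 208 as deposited and 6 and 1143 with scaling on the added controls.

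The design text keeps probe sets at least 3-fold different from parental cells in any condition, and gives 1431 of them after a filter on Present flags, which the files used here do not carry. Without that filter 2331 probe sets passed in the centred values and 3035 in the values as deposited, or 1576 of the latter with the brightest array at 200 units or more. Simulated unchanged arrays against 1 simulated parental array passed a mean of 391 probe sets in any condition, so noise could account for part of the 2331. Of the 2331, 34 were higher and 87 lower on all 3 arrays, where the simulated arrays gave means of 1.39 and 3.74. These means contain normal noise of a shared parental array. They leave out noise with wider tails and real differences of the parental line, so part of the excess may still come from the shared parental array. When the 2331 were grouped into 15 clusters by K-means, both probe sets of Ccl9 and 1 of the 2 of Ccl6 fell in a cluster of 29 probe sets with median log2 ratios of 0.36 with BCR-ABL, 3.90 with ICSBP and 3.99 with both. The other Ccl6 probe set fell in a cluster of 113 with medians of 0.01, 1.74 and 0.20 in that order. Lyz2, Ctss, Mpeg1, Lcn2, Ghr and Fcer1a had probe sets in the cluster of 29. Another cluster, of 8 probe sets with medians of -5.36, -2.14 and -5.17, held Prg2, Epx, Ngp, Cma1, F13a1 and Greb1.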

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

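Of the tests in this part, the comparison of the Mycn probe sets and the test of the higher and lower split were chosen only after the result was seen, as were the values as deposited and the scaling on the added controls, and the tests of a fault of the parental array were set before their results were seen. The gene lists, thresholds and naming rule were fixed before the data were examined.

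Some genes were at least 3-fold changed by a construct in opposite directions in the 2 backgrounds, and these differences were not tested. For ICSBP 9 genes were lower without and higher with BCR-ABL, and 0 the reverse. For BCR-ABL 10 genes were lower without and higher with ICSBP, and 1 the reverse. The 9 and the 10 share Boll, Cryzl2, Klhdc8a, Mapk15, Stab2 and Vgll2, so they are not separate results. The 5 genes given with values here are those with opposite calls that the naming rule covers. The ICSBP effect on Il1b, which encodes an inflammatory cytokine, was -1.67 (log2) without BCR-ABL and 2.41 with it, and that on Ngp was -2.61 and at least 1.94. The BCR-ABL effect on Dab2ip, a RAS GTPase-activating protein, was -1.64 without ICSBP and 1.77 with it, and that on Tlr9, a receptor for unmethylated DNA, was -2.32 or lower and 1.68. For Ccl6 the BCR-ABL effect was at least 1.78 without and -1.74 with ICSBP, the former in 1 probe set while the other read -0.98. With a floor of 100 the opposite calls of all 5 ended, since 1 or both ratios fell under 3-fold. Il1b without BCR-ABL was then -0.77, Ngp with BCR-ABL 0.94, Dab2ip -0.66 without and 1.15 with ICSBP, Tlr9 without ICSBP -1.32, and Ccl6 without ICSBP 0.78. By the median of its probe sets Ccl6 was 0.40, and Dab2ip -0.56 and 1.41. After quantile normalization Il1b was -1.48, Dab2ip -1.35 and 1.55, and Tlr9 with ICSBP 1.52. With scaling on the added controls Il1b was -1.35, Ngp 1.12, Dab2ip without ICSBP -0.83 and Tlr9 without ICSBP -1.49.

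Signals outside the named genes also differed. Among probe sets without a single gene symbol, 9 were at least 3-fold higher with BCR-ABL than in parental cells, 23 with ICSBP and 66 with both, while 66, 65 and 56 were at least 3-fold lower. The added bacterial and phage control probe sets, which are not cell transcripts, had median log2 ratios to parental after centring of 0.81 with BCR-ABL, 0.46 with ICSBP and 0.34 with both.

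The brightest Mycn probe set was over 200-fold brighter on the 3 other arrays than on the parental array. A higher level of all Mycn transcripts is argued against by the gene's other probe sets, whose highest log2 ratio was 1.0003. A fault of the parental array of over 50-fold on many probe sets is argued against too, since 0 other probe sets were over 50-fold brighter on all 3 arrays. A smaller or local fault would not show in this test, so it stays open. Sequence shared by the constructs or their vector and read by this probe set could produce the pattern, as could a Mycn transcript that the others miss. Neither was tested.

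In the centred values, more genes were higher than lower on the BCR-ABL plus ICSBP array against the BCR-ABL array. The share higher among the called genes was 81.9%, and 57.7% after quantile normalization, which gives all arrays 1 distribution and so draws any such split towards balance. Whether the scaling of the arrays accounts for the excess was therefore not tested. The values as deposited gave 47.9%, which is no excess of higher genes, and scaling on the added controls 96.9%. Both the direction and the size of the split therefore depend on a scaling that these arrays do not settle. That ICSBP goes with more higher than lower genes in either background stays open, because the share higher for ICSBP against parental ran from 47.2% to 64.2% over 3 scalings and was 9.09% with scaling on the added controls.

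For BCR-ABL against parental, 23 genes were at least 5-fold lower, Prg2 and Epx among them. A fault of the parental array predicts no difference between the other arrays, yet the same genes had a median log2 ratio of -1.15 for both constructs against ICSBP alone (SD over genes 1.62), and 19 of 23 were lower. This argues against such a fault as the whole source. An effect of BCR-ABL and chance differences between separately grown lines, with 1 line per condition, both stay open and untested.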

How the results depend on the processing

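The values as deposited and the scaling on the added controls were tried only after seeing the data, and the other alternatives were planned. Of 256 named ratios of at least 3-fold, 157 stayed at least 3-fold under all alternatives run and 99 did not under 1 or more. Over 1738 alternative values of these ratios, 1728 kept their direction and 10 reversed. These counts are no check of array scaling for the values as deposited and the added controls. Ratios under both were taken relative to the median of all genes, which removes most of a shift of a whole array. With that shift left in, scaling on the added controls gave 6 genes at least 3-fold higher for BCR-ABL against parental, against 96 centred. The minimum for the brighter array left a ratio unchanged or dropped it, so it could not end a call. Prg2, Epx, Pf4 and Ngp for BCR-ABL against parental, and Ccl9, Ccl6, Lyz2, Ctss, Mpeg1, Itgam and Stub1 for ICSBP against parental, were among the 157. A floor of 25 was not run because the deposited floor was 50, and the planned centring became the main setting. With 1 array per condition no array could be left out. No paired analysis was possible because the conditions share only replicate number 1. The median of all genes over the 5 comparisons, in the order below, was 0.34, 0.23, -0.42, -0.32 and -0.06 as deposited and -0.92, -0.51, 0.62, 0.21 and -0.27 with scaling on the added controls, and gene and list values under these are relative to it. Signals near the floor limit many folds to bounds.

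Counts below are in the order BCR-ABL against parental, ICSBP against parental, both against BCR-ABL, both against ICSBP, both against parental, the difference of the ICSBP effect, and probe sets in any condition. With a floor of 100 they were 85, 102, 133, 79, 148, 230.0 and 495, lower because folds against the floor shrink. With the brighter array at 200 or more they were 157, 165, 286, 203, 316, 379 and 1111, from fewer genes. A threshold of 2 gave 1492, 1529, 2182, 2073, 2225, 2631 and 9276, and a threshold of 5 gave 36, 60, 85, 48, 87, 314 and 280.0. The median of a gene's probe sets gave 372 for both against BCR-ABL and 314 for both against ICSBP. The values as deposited gave 514 for BCR-ABL and 508 for ICSBP against parental. Scaling on the added controls gave 1149 and 495 for these, 2931 for the difference of effects and 3953 probe sets. For the last 3 alternatives the cause was not tested.

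Pearson's r across genes between the ICSBP effects in both backgrounds, and between the BCR-ABL effects, was 0.223 and 0.188 with a floor of 100, 0.234 and 0.178 after quantile normalization, 0.235 and 0.181 at 200 or more, 0.156 and 0.0939 as deposited, and 0.231 and 0.179 with scaling on the added controls. Between the mean effects of the constructs it was -0.0190 with a floor of 100, 0.0720 after quantile normalization, -0.00543 as deposited and 0.0599 with scaling on the added controls. The cause was not tested.

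Some log2 values reversed. By the median of probe sets, Zap70 was 1.04 for both against BCR-ABL and 1.01 for both against ICSBP, and Acta2 -0.48 for the former. List medians by the same alternative were -0.0329 for STAT5 targets with BCR-ABL against parental, -0.0891 for erythroid and megakaryocyte markers with both against BCR-ABL, and 0.00596 for T and NK cell markers with both against parental. Without probe sets shared between transcripts, Lyz1 was -0.42 for BCR-ABL, -1.41 for ICSBP and -0.69 for both against parental, and -0.27 for both against BCR-ABL, and Acta2 was -0.48 for the last. In these cases other probe sets of the gene stood in. At 200 or more the neutrophil median for ICSBP against parental was 1.24 over 3 members, and the erythroid and megakaryocyte median for both against BCR-ABL was -0.0630. Both moved because dimmer members were left out. As deposited, Pax5 was -0.87 for both against BCR-ABL and -1.08 for both against parental, where another of its probe sets was the brightest. With scaling on the added controls the mast cell and basophil median for BCR-ABL against parental was 0.12, and the chemokine receptor median for both against BCR-ABL was -0.0767. The cause of these last changes, with scaling on the added controls, was not tested.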

Other observations

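The values as deposited and the scaling on the added controls were chosen only after the result was seen, and no explanation is tested in this part. Genes of cell division did not pass the threshold: 0 of 35 S and G2-M genes were at least 3-fold higher or lower in each of the 5 comparisons, with medians of 0.07 (percentile 6.13) for BCR-ABL and 0.09 (percentile 20.6) for ICSBP against parental. Bcl2, an inhibitor of apoptosis, was 2.28-fold lower with BCR-ABL, 2.34-fold lower with ICSBP and 2.92-fold lower with both than in parental cells, in each case by all 5 probe sets and under the 3-fold threshold. Bcl2l1, which encodes BCL-XL, was 2.01-fold higher with BCR-ABL, and 0 of 15 BCL2 family genes passed the threshold there. Among cell cycle inhibitors Ccng2, cyclin G2, was 3.94-fold higher with BCR-ABL and 4.14-fold higher with ICSBP, the 1 of 14 members called in each. The medians of that list were 0.40 and 0.28, at percentiles 99.8 and 98.4. The ratios of Ccng2 and of Bcl2 given here all share the parental array, so their agreement between constructs can come from that array.

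Few genes of cell metabolism passed the threshold with BCR-ABL against parental. The medians of several of these lists were nevertheless high among random lists, as were those of many other lists in this comparison. Bnip3 and Ankrd37, both induced by hypoxia, were 3.11-fold higher and 4.73-fold higher with BCR-ABL, the 2 of 22 glycolysis and hypoxia genes called (median 0.33, percentile 99.8), though Bnip3 was 1.55 after quantile normalization. With ICSBP against the same parental array Ankrd37 was 5.56-fold higher, and the list's median was 0.32 (percentile 99.8). With both constructs Ankrd37 was 4.59-fold higher, or 1.56 with a floor of 100 (log2). Cholesterol synthesis had 0 of 20 members called with BCR-ABL (median 0.33, percentile 99.9), with Fdft1, squalene synthase, 2.13-fold higher in 4 of 4 probe sets. For p53 targets the count was 0 of 17 (median 0.41, percentile 99.95), and for the amino acid and ER stress response 0 of 23 (median 0.26, percentile 94.9, or -0.02 after quantile normalization). Of 19 chromatin genes 1 was lower with BCR-ABL, Cbx7, whose fold is a bound that fell under the threshold with a floor of 100 (-0.83). Housekeeping genes had 0 of 12 called in each comparison.

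Other immune lists had few called members for both constructs against BCR-ABL alone. Icam2, an adhesion molecule, was 3.01-fold higher, 1 of 21 costimulation genes called (median -0.29, percentile 0.150), and 1.57 in the values as deposited. Of interferon-stimulated genes 1 of 31 was called, the RNA sensor regulator Dhx58 (3.05-fold, 0.69 by the median of its probe sets), with a median of 0.12 (percentile 51.2). Among reported IRF8 targets 2 of 18 were higher, Tlr9 (at least 6.27-fold) and Trem2 (3.12-fold, 0.82 by the median of its probe sets), with a median of 0.50 (percentile 94.0). Dendritic cell markers had 0 of 10 called (median 0.40, percentile 67.4, or -0.01 with scaling on the added controls). The B-lineage list had 2 of 21 higher, Pax5 and Cd22, and 1 lower, Cd79a (3.84-fold). Pax5 was -0.87 in the values as deposited, where another of its probe sets was the brightest, and Cd22 was 0.65 with a floor of 100. The median of the list was 0.35 (percentile 79.9), or -0.07 after quantile normalization. The T and NK cell list had 2 of 11 lower, Lat and Zap70, the latter reversed by the median of its probe sets (1.04). Stromal genes had 2 of 11 higher, Fn1, which was 0.74 with a floor of 100, and Acta2, which reversed without probe sets shared between transcripts (-0.48). Adhesion and migration genes had 2 of 25 higher, Itgam and Icam2, and 1 lower, Itgal. For ICSBP against parental, 0 of 19 reported IRF8 targets were higher and 0 lower (median 0.24, percentile 94.4). Of interferon-stimulated genes 1 of 30 was higher there and 0 lower (median 0.23, percentile 98.5). The interferon list was as high for BCR-ABL against the same parental array (0.25, percentile 99.3).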
